A study of Mus musculus with 20 samples.

How the data were processed

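RNA-seq and ATAC-seq libraries were made from eGFP-positive cardiac fibroblasts of the Tcf21 lineage, 2 libraries per assay from uninjured hearts and from hearts at day 3, day 7, week 2 and week 4 after MI. Per the labels, tamoxifen (75 mg/kg/day for 5 days) induced the lineage mark, hearts were digested with collagenase and dispase, the sort gate was set on eGFP-negative wild-type cells, and RNA came from 10000 sorted cells. Groups were read from the sample labels, and 0 columns of the count table stayed unmapped.

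The deposited RNA table holds expected counts per Ensembl gene, that is read counts estimated per gene, not scaled between libraries, as their decimals and unequal totals show. The submitters' processing notes list Trim Galore 0.6, FastQC, STAR 2.5.3a, DESeq2, Bowtie2 2.3, MACS2 and the builds mm10 and GRCm38 without saying what each was used for. The program that estimated the counts and the strand that was counted are not given in the sources used here. Each deposited ATAC-seq file is a peak list of 1 library in narrowPeak format. By the column order of that format, the deposited lists give each peak a fold enrichment over local background (a ratio), the −log10 of its p and q, and the summit's offset from the peak start. The score column of the deposited lists equals the whole part of 10 times the −log10 q. The thresholds and filters behind the peaks are not given in the sources used here.

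The table holds 25746 genes, of which 7472 have no count in any library. Symbols were those of the deposited table, and 25635 identifiers were found in a table of gene names. Library totals were 16397211 to 21043997 counts. Reads amplified by PCR without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. A gene with no counts in a group was given a floor of 3 counts per library, and folds against it are lower bounds. A group with 1 to 3 counts was given its counts, with an interval where a ratio is printed. Reads shared between related genes are uncertain for families such as the ribosomal protein and Oas genes.

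Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr by group (14968 genes kept), a robust quasi-likelihood fit of all 10 libraries with group as the only factor (5 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05 within each contrast. Contrasts were each time against uninjured, the consecutive times, and week 4 against day 7. A contrast of week 4 against day 3 was added after the data were seen. The SE of a log2 fold change comes from the same fit, and CPM are given as mean ± SD over the 2 libraries of a group. Counts of all 10 libraries were simulated from the uninjured means and from gene-wise dispersions fitted over all groups (14968 genes). Changes were planted at day 3 in genes drawn at random, whatever their expression level. There edgeR recovered 5% of 100 genes changed 2-fold and 25% of 100 changed 4-fold, with 3 false calls among 33. DESeq2 1.42.0 recovered 16% and 41%, with 57 false calls among 119. The other 5 DESeq2 calls were members of a list of 30 genes planted with a smaller change. Simulations with no changed gene gave 0, 0 and 1 edgeR calls for day 7, week 2 and week 4 against uninjured. The edgeR test had been fixed as the main one beforehand, and DESeq2 serves as an alternative only. The simulation was a single draw from dispersions fitted by edgeR, for the genes that its filter kept. DESeq2 was run on the unfiltered counts of the data, so the simulation does not give its error rate there.

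The 32 gene lists of pathways, matrix groups and markers of other cell types, the named-gene rule, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera (limma 3.58.1; correlation 0.01) with adjustment over all 32 lists and 8 contrasts, and again with an estimated correlation and with fry. Of 127 list calls none held at 0.05 with an estimated correlation, where the lowest adjusted p was 0.062, and 48 were also called by fry in the same direction. For a simulated list of 30 changed genes, drawn independently of each other, camera gave p = 2.1e-13 at the fixed correlation and p = 4e-04 with an estimated one. The estimated setting thus costs power even without correlation. A call lost there is neither shown to rest on correlation nor shown to hold. The named-gene rule took, for each time against uninjured, the 6 rising and 6 falling genes of largest log2 fold change among those that passed. They needed a mean log2 CPM of 4 or more and both libraries beyond both uninjured libraries, and predicted, mitochondrial and ribosomal genes were left out. For contrasts between times it took 4 and 4, and for each list described up to 4 members that passed. Tcf21, Acta2, Postn, Col1a1, Col3a1, Mki67, Comp, Chad, Cilp2, Fmod, Runx1 and Meox1 were to be reported whatever their result. For ATAC-seq the rule took 3 gained and 3 lost regions per time by the mean percentile of −log10 q.

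Peaks on chromosomes 1 to 19, X and Y were merged into regions at an overlap of 1 bp or more, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peak files carry no reads, so regions were compared by presence of a peak only, and the depth of the ATAC-seq libraries is unknown. Gained and lost counts were set beside the splits that pair 1 library of each group. Similarity within groups was tested over all partitions of the 10 libraries into pairs (exact, one-sided). A region was assigned to the nearest gene span within 100 kb. The annotation used gave no strand and no genome sequence was held, so distances are to gene spans or their ends (1 kb) and not to transcription start sites, and exons and introns were not used. Genes that changed and regions that changed were compared with Fisher's exact test (two-sided), adjusted over 16 planned tests, and apart from these over 16 that were not planned. No list of regions prone to spurious signal was used. Transcription factor motifs were not analysed here. In simulated peak lists for day 3 against uninjured, 80.87% of planted gained regions and 80.25% of planted lost regions were recovered, where 81% was to be found, with 176 falsely gained. Each simulated library detected each of its regions independently and with the same chance, which sets the 81% by construction. The simulation thus checks the counting of regions, and gives no rate of recovery or false gain for the deposited lists.

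Alternatives covered scaling, filters, the fit of 2 groups alone, DESeq2, a minimum fold and leaving out each library. For peaks and regions they covered equal peak numbers, a stricter q, another overlap, windows of equal width centred on summits, and other distances. With an RNA library left out, the count filter was rerun with a group of 1 library and kept 15960 to 16035 genes instead of 14968. A call lost in that way can reflect the changed set of tested genes as well as the library left out. A term for Y-linked reads, strata by region number, and leaving out the Y chromosome's genes, some library codes or marker genes of other cells were chosen after seeing the data. The replicate numbers were checked for pairing across groups: deviations from group means correlated at −0.018 to 0.029 over the 10 pairs of groups, so the numbers carry no pairing and the replicate block is an alternative only.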

Results

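Cardiac fibroblasts of the Tcf21 lineage were sorted from mouse hearts as eGFP-positive cells and profiled by RNA-seq and by ATAC-seq, an assay in which a transposase inserts adapters into accessible chromatin. Tcf21 encodes a transcription factor of resident cardiac fibroblasts, and the heritable label marks those cells and their descendants. Each assay had 2 libraries from uninjured hearts and 2 libraries each from hearts at day 3, day 7, week 2 and week 4 after myocardial infarction (MI). The series was set up to relate accessible chromatin to gene expression in these cells before and after MI. The RNA libraries held 16397211 to 21043997 expected counts, and the ATAC-seq peak lists held 63901 to 107798 peaks on the chromosomes used. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The RNA libraries of day 3, day 7 and week 4 are an exception: within each of these groups 1 library had Y-linked reads and the other next to none, so they were not repeats of the same animal or pool.

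On average, libraries of the same group resembled each other more than libraries of different groups in both assays. The mean Pearson correlation of log CPM (counts scaled to a common library total) over 14968 tested genes was 0.906 within groups and 0.86 between groups. An exact one-sided permutation test over all partitions of the 10 libraries into pairs gave p = 0.00106, the smallest it can give. For ATAC-seq the mean Jaccard index, the shared length of 2 peak lists over their joint length, was 0.666 within groups and 0.58 between groups, with p = 0.00106 in the same exact test. Single pairs overlapped: the lowest value within a group was 0.882 for RNA and 0.614 for ATAC-seq, both at day 7, and the highest between groups 0.906 and 0.661. Day 7 replicate 1 and week 2 replicate 1 in RNA, and day 7 replicate 1, day 7 replicate 2 and week 4 replicates 1 and 2 in ATAC-seq, had a closer library in another group than in their own. The first principal component of the RNA data held 26.2% of the variance and set the day 3 and day 7 libraries, all above 40, apart from the other libraries, all below 0. The third component held 13.3% of the variance and set week 2 replicate 2, at −132.1, apart from all other libraries, at −18.12 to 55.37. The code of that library, B31, begins with B, and those of all other RNA libraries with C. In edgeR's quasi-likelihood test 2349 genes differed among the 5 groups. Several library properties moved with the groups. Haemoglobin genes took 0.423% and 0.597% of the counts in the uninjured libraries and 0.0144% to 0.382% after MI. Mitochondrially encoded genes took 2.66% and 2.71% in the uninjured libraries and 0.987% to 1.49% in 7 of the libraries after MI, but 4.21% in week 2 replicate 1. Genes of the Y chromosome took 0.0124% to 0.0429% of the counts in day 3 replicate 1, day 7 replicate 2, both week 2 libraries and week 4 replicate 2, and at most 6.24e-05% in the other 5, which include both uninjured libraries.

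**Figure D1:**
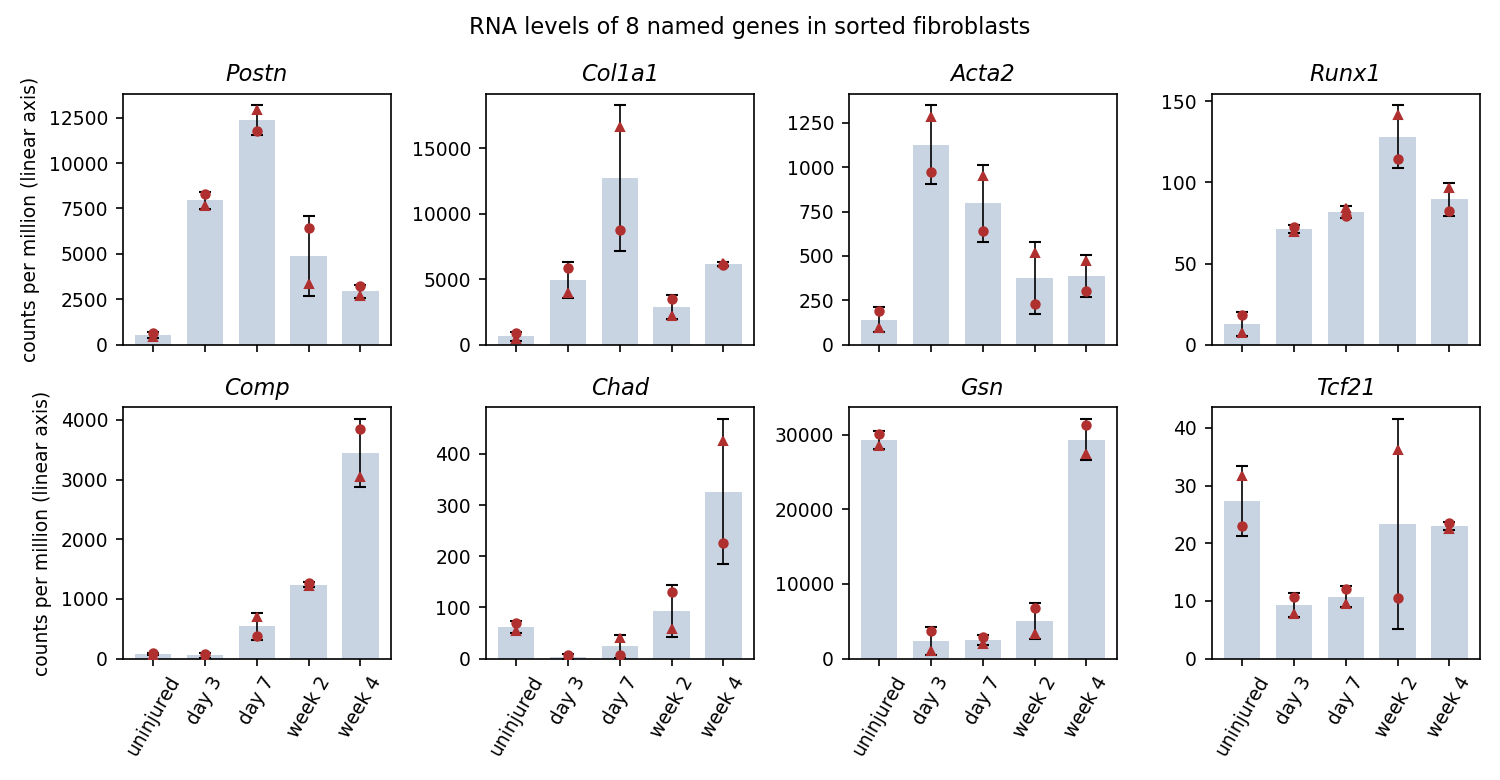
CPM (linear axes) of 8 named genes in each RNA-seq library by group, with bars for the mean, error bars for the SD and points for the 2 libraries of a group. Postn rose from a mean of 530 CPM in uninjured hearts to 12400 CPM at day 7, and Comp from 73.9 CPM to 3440 CPM at week 4, while the differences of Tcf21 from uninjured passed the test at none of the 4 times.

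At day 3 after MI the sorted fibroblasts carried higher RNA levels of many cell cycle, matrix and contractile genes and lower levels of many genes of the resting fibroblast. Periostin (Postn, ENSMUSG00000027750), a matricellular protein gene on chromosome 3 at 54361109 to 54391037, rose to 7950 ± 460 CPM from 530 ± 141 CPM in uninjured hearts (mean ± SD, n = 2), a log2 fold change of 3.91 ± 0.34 (SE). Smooth muscle actin (Acta2) rose to 1130 ± 220 from 141 ± 70.1 CPM and the collagen gene Col1a1 to 4930 ± 1350 from 659 ± 345 CPM. The transcription factor gene Runx1 rose to 71.2 ± 2.31 from 12.8 ± 7.51 CPM. Of the most strongly rising genes, the receptor gene Gpr176 rose by 8.83 ± 0.50 on the log2 scale and the chemokine gene Ccl9 by 7.94 ± 0.57. The matrix glycoprotein gene Tnc rose by 7.90 ± 0.64, and Pclaf, which encodes a PCNA-binding protein, by 7.82 ± 0.68. Steap1 stood at 82.8 CPM at day 3, against 3 and 0 counts in the uninjured libraries. The retinol dehydrogenase gene Adh1, the IGF-binding protein gene Igfbp3 and the glypican gene Gpc3 had log2 fold changes of −3.84 ± 0.73, −4.39 ± 0.67 and −3.77 ± 0.38. The rule for named genes also picked Hp, Cyyr1, Cytl1 and Inmt, with log2 fold changes of 8.56, −4.60, −4.50 and −4.41. Each of these 4 calls was lost without uninjured replicate 1 and also without uninjured replicate 2, and the last 3 without other libraries as well.

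Of the 35 cell cycle genes tested, 26 rose at day 3 and none fell (34 rose when adjusted over the list alone), with a median log2 fold change of 4.42. Camera gave adjusted p = 4e-36, and adjusted p = 0.062 with an estimated correlation. The mitotic kinase gene Cdk1 stood at 156 ± 32.4 CPM against 2.43 ± 3.28 CPM, a call lost without either day 3 or either week 4 library. The spindle protein gene Hmmr stood at 121 ± 16.7 against 2.08 ± 1.28 CPM, a call lost without uninjured replicate 2. Mki67, a proliferation marker, had 114 ± 1.53 CPM at day 3 and 5.38 ± 7.46 CPM in uninjured hearts, which did not pass (edgeR adjusted p = 0.092). Among 34 genes of fibrillar collagens and large matrix glycoproteins 16 rose and 1 fell (20 and 2 adjusted over the list alone; median log2 fold change 1.40; camera adjusted p = 3.7e-17, and adjusted p = 0.22 with an estimated correlation). Of 26 genes of collagen processing and crosslinking 9 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 5e-10, and adjusted p = 0.062 with an estimated correlation). Lysyl oxidase (Lox) stood at 814 ± 31.6 against 46.7 ± 11.3 CPM and the prolyl hydroxylase subunit gene P4ha3 at 81.2 ± 7.66 against 2.97 ± 0.177 CPM. Contractile and myofibroblast genes rose in 14 of 24 cases (18 adjusted over the list alone; camera adjusted p = 7.9e-18, and adjusted p = 0.14 with an estimated correlation). Cthrc1, a secreted protein gene, stood at 1480 ± 231 against 12.9 ± 3.73 CPM.

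Genes fixed as resident fibroblast genes fell in 18 of 31 cases at day 3 (26 adjusted over the list alone; median log2 fold change −1.87). Camera gave adjusted p = 4.9e-17, and adjusted p = 0.21 with an estimated correlation. The vitronectin gene Vtn stood at 3.11 ± 0.62 CPM against 34.5 ± 8.29 CPM. Gelsolin (Gsn), an actin-severing protein gene, stood at 2350 ± 1830 against 29300 ± 1150 CPM, a call lost without either uninjured library. Tcf21 had 9.28 ± 2.07 CPM against 27.4 ± 6.04 CPM, which did not pass (edgeR adjusted p = 0.086). Of the small leucine-rich proteoglycan list, decorin (Dcn) had a log2 fold change of −1.66 ± 0.29 and asporin (Aspn) of 1.32 ± 0.22. The list as a whole missed the threshold (edgeR's camera method, adjusted p = 0.051), with 2 members rising and 4 falling (2 and 7 adjusted over the list alone). AP-1 and immediate-early genes fell in 7 of 28 cases and rose in 1 (camera adjusted p = 9.4e-05, and adjusted p = 0.55 with an estimated correlation). Jun stood at 667 ± 182 against 2460 ± 393 CPM and Fosl1, the 1 that rose, at 23.6 ± 2.56 against 1.10 ± 0.949 CPM, a call lost without uninjured replicate 1. The cartilage and tendon list was not called at day 3 (1 rose and 3 fell of 27; edgeR's camera method, adjusted p = 0.38).

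Of 30 cytokine and chemokine genes 11 rose and 1 fell at day 3 (camera adjusted p = 1.2e-07, and adjusted p = 0.21 with an estimated correlation). Osteopontin (Spp1) stood at 1350 ± 487 against 27.8 ± 8.17 CPM. Of 32 interferon-stimulated genes 17 rose (20 adjusted over the list alone; median log2 fold change 1.86, or 1.77 with the member at 0 counts in a group set to its floor; camera adjusted p = 6.3e-14, and adjusted p = 0.22 with an estimated correlation). The ubiquitin-like modifier gene Isg15 stood at 126 ± 12.4 against 9.95 ± 5.78 CPM. Ribosomal protein genes rose in 37 of 40 cases (40 adjusted over the list alone; median log2 fold change 1.27; camera adjusted p = 1.1e-31, and adjusted p = 0.23 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose in 9 of 38 cases (camera adjusted p = 3.2e-06, and adjusted p = 0.44 with an estimated correlation) and glycolysis genes in 8 of 22 (camera adjusted p = 0.00025, and adjusted p = 0.28 with an estimated correlation). Genes of protein folding in the endoplasmic reticulum rose in 8 and fell in 4 of 31 cases (camera adjusted p = 0.012, and adjusted p = 0.41 with an estimated correlation), and basement membrane genes fell in 4 of 19 (camera adjusted p = 0.028, and adjusted p = 0.59 with an estimated correlation). The first of these calls was lost without uninjured replicate 2 or day 3 replicate 2, and the second without any 1 of 4 libraries.

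Marker genes of other cell types moved as well at day 3. Of 20 macrophage and monocyte markers 14 rose (18 adjusted over the list alone), with a median log2 fold change of 3.98 and a summed level of 986 and 1674 CPM against 127 and 129 CPM in the uninjured libraries (camera adjusted p = 1.7e-22, and adjusted p = 0.12 with an estimated correlation). Of 16 endothelial markers 7 fell (9 adjusted over the list alone; median log2 fold change −1.60; camera adjusted p = 5.7e-07, and adjusted p = 0.28 with an estimated correlation). Lists with a lower level at day 3 and few members passing were pericyte and smooth muscle (1 rose and 4 fell of 14), cardiomyocyte (1 rose and 1 fell of 18), erythroid (0 of 7) and mitochondrially encoded genes (0 of 13), with camera adjusted p of 0.013, 0.012, 0.00036 and 6e-04, and adjusted p = 0.43, 0.46, 0.41 and 0.59 with an estimated correlation. Adjusted over the list alone, 5 erythroid genes fell. The pericyte call was lost without uninjured replicate 1 and the cardiomyocyte call without day 3 replicate 2.

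In all, 1764 of 14968 genes passed at day 3 against uninjured, 1106 higher and 658 lower, at a Benjamini-Hochberg adjusted p under 0.05 in edgeR. DESeq2 called 2830 genes. Without uninjured replicate 1, uninjured replicate 2 or day 3 replicate 2, edgeR called 958, 748 and 677, and 62 of the 111 named genes that passed kept their call with each of the 10 libraries left out in turn.

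At day 7 several collagen and matrix genes stood at their highest mean level of the 5 groups. Postn reached 12400 ± 821 CPM, Col1a1 (ENSMUSG00000001506) 12700 ± 5570 CPM and Col3a1 10900 ± 1740 CPM, log2 fold changes against uninjured of 4.54 ± 0.35, 4.27 ± 0.46 and 2.94 ± 0.40. Of 34 genes of fibrillar collagens and large matrix glycoproteins 24 rose (30 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.1e-51, and adjusted p = 0.096 with an estimated correlation). Col11a1 stood at 272 ± 9.86 against 3.58 ± 3.24 CPM. Crosslinking genes rose in 7 of 26 cases and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 8e-13, and adjusted p = 0.062 with an estimated correlation). Lox stood at 1320 ± 374 CPM. Contractile genes rose in 11 of 24 cases (15 adjusted over the list alone; camera adjusted p = 4.6e-18, and adjusted p = 0.14 with an estimated correlation), and Acta2 stood at 796 ± 218 CPM, a call lost without uninjured replicate 2 or day 7 replicate 2. Of 27 cartilage and tendon matrix genes 7 rose, while 16 stood above and 6 below both uninjured libraries (12 rose and 2 fell adjusted over the list alone; median log2 fold change 2.34; camera adjusted p = 0.00013, and adjusted p = 0.37 with an estimated correlation). Matn3, which encodes the cartilage protein matrilin 3, was at least 74.1-fold higher than in the uninjured libraries, where it had no counts. Col2a1, the main collagen gene of cartilage, was at least 226-fold higher by the same floor, a call lost without either uninjured library, day 7 replicate 2 or either week 4 library. Comp, a cartilage matrix gene, rose to 540 ± 229 from 73.9 ± 17.6 CPM, a call lost without either uninjured library or day 7 replicate 2.

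Cthrc1 rose by 7.76 ± 0.36 on the log2 scale at day 7, Gpr176 by 8.86 ± 0.50, and the myeloid genes Fcrls and Laptm5 by 7.62 ± 0.84 and 7.60 ± 1.06. Kif26b stood at 51.6 CPM against 0 and 3 counts in the uninjured libraries, and Hp rose by 10.71 ± 1.30, a call lost without either uninjured library. The cell adhesion gene Lsamp, the eotaxin gene Ccl11 and Adh1 had log2 fold changes of −4.87 ± 0.55, −4.73 ± 0.69 and −4.11 ± 0.74, the last lost without either day 7 library. Inmt, Scara5 and Myoc had log2 fold changes of −5.84, −4.37 and −4.03, and each call was lost without either uninjured library and without others, 9 of the 10 in the case of Scara5. Resident fibroblast genes fell in 15 of 31 cases (26 adjusted over the list alone; median log2 fold change −1.92; camera adjusted p = 1.2e-18, and adjusted p = 0.21 with an estimated correlation).

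Cell cycle genes rose in 10 of 35 cases at day 7 (19 adjusted over the list alone; median log2 fold change 2.18; camera adjusted p = 1.7e-14, and adjusted p = 0.13 with an estimated correlation), interferon genes in 8 of 32 (camera adjusted p = 4.3e-07, and adjusted p = 0.39 with an estimated correlation) and ribosomal protein genes in 15 of 40 (35 adjusted over the list alone; camera adjusted p = 7.3e-14, and adjusted p = 0.41 with an estimated correlation). The Wnt list had a camera direction of up (adjusted p = 0.005, and adjusted p = 0.16 with an estimated correlation) with 5 genes rising and 1 falling of 23, but a median log2 fold change of −0.03, and the call was lost with any 1 of the 10 libraries left out. Its rising members included Ccn4, a secreted matricellular protein gene, at 325 ± 49.5 against 4.36 ± 2.40 CPM and the secreted Wnt modulator gene Sfrp2 at 2020 ± 36.4 against 108 ± 33.6 CPM. Cytokine genes (4 rose and 1 fell of 30) and glycolysis genes (3 rose of 22) were called up, with camera adjusted p of 0.008 and 0.018, and adjusted p = 0.46 and 0.44 with an estimated correlation. AP-1 genes (3 fell of 28) and heat shock genes (2 fell of 17) were called down, with camera adjusted p of 0.0034 and 0.018, and adjusted p = 0.64 and 0.53 with an estimated correlation. The cytokine call was lost without uninjured replicate 1 or day 7 replicate 2, and the glycolysis call without day 7 replicate 2. Those of the AP-1 and heat shock genes were lost without uninjured replicate 2 or day 7 replicate 1. Macrophage markers rose in 17 of 20 cases (19 adjusted over the list alone; median log2 fold change 5.58; camera adjusted p = 1.7e-42, and adjusted p = 0.062 with an estimated correlation) and summed to 3028 and 4918 CPM. Endothelial markers rose in 6 of 16 cases and fell in 1 (camera adjusted p = 1.9e-05, and adjusted p = 0.37 with an estimated correlation). Cardiomyocyte, erythroid and mitochondrially encoded genes were called down, with camera adjusted p of 0.038, 0.019 and 0.0045, and adjusted p = 0.59, 0.59 and 0.63 with an estimated correlation. All 3 were lost without day 7 replicate 1, and the cardiomyocyte and erythroid calls also without uninjured replicate 2.

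In all 1070 genes passed in edgeR at day 7, 657 higher and 413 lower than in uninjured hearts, and DESeq2 called 2000. Of the 98 named genes that passed, 47 kept their call with each library left out in turn. With the presence of Y-linked reads as a further term, added after the data were seen, edgeR called 587. Without uninjured replicate 1, uninjured replicate 2 or day 7 replicate 2 it called 604, 362 and 312, and in a fit of the 2 groups alone 635.

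Of 34 fibrillar collagen and glycoprotein genes 18 rose and 1 fell at week 2 (24 and 1 adjusted over the list alone; median log2 fold change 1.83; camera adjusted p = 3.4e-45, and adjusted p = 0.12 with an estimated correlation). Cartilage and tendon genes rose in 5 of 27 cases (12 rose and 1 fell adjusted over the list alone; median log2 fold change 2.71; camera adjusted p = 1.7e-11, and adjusted p = 0.16 with an estimated correlation). Comp was higher by 4.07 ± 0.58 on the log2 scale, a call lost without either uninjured library or week 2 replicate 2, and Matn3 at least 104-fold above its uninjured floor. Wnt genes rose in 5 of 23 cases, with 9 above and 5 below both uninjured libraries (8 rose and 1 fell adjusted over the list alone; median log2 fold change 0.44; camera adjusted p = 3.3e-08, and adjusted p = 0.062 with an estimated correlation). Sfrp2 stood at 3860 ± 920 CPM and Ccn5 at 1430 ± 256 against 90.5 ± 19.1 CPM. Runx1 had its highest mean level of the 5 groups, 128 ± 19.4 CPM, and C1qtnf3, a secreted protein gene, stood at 665 ± 140 against 7.64 ± 1.48 CPM, a call lost without uninjured replicate 2.

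TGF-beta and BMP genes rose in 6 of 30 cases and fell in 1 at week 2 (camera adjusted p = 0.00011, and adjusted p = 0.21 with an estimated correlation). The latent TGF-beta binding protein gene Ltbp2 was higher by 4.28 ± 0.35 on the log2 scale. Crosslinking (4 of 26) and contractile genes (3 of 24, or 7 adjusted over the list alone) rose with camera adjusted p of 1.5e-06 and 7.7e-12, and adjusted p = 0.12 and 0.21 with an estimated correlation. Resident fibroblast genes fell in 6 of 31 cases (20 adjusted over the list alone; median log2 fold change −1.47; camera adjusted p = 5.2e-21, and adjusted p = 0.20 with an estimated correlation). Pdgfra, the receptor gene often used as a fibroblast marker, stood at 217 ± 80.6 against 755 ± 33.9 CPM, a call lost without week 2 replicate 2. Gfra1 and Lsamp had log2 fold changes of −3.57 ± 0.33 and −3.52 ± 0.52, and Icosl of −3.95 ± 0.58, the last lost without week 2 replicate 2. Acta2 stood at 374 ± 203 CPM, which did not pass (edgeR adjusted p = 0.21), and the cell cycle list was not called (camera adjusted p = 0.87). Within it the kinesin gene Cenpe had no counts at week 2 and was at least 32.2-fold lower than in uninjured hearts. Kif2c, a mitotic kinesin gene outside the list, had 1 count in each week 2 library, a call lost without week 2 replicate 2. Macrophage markers rose in 9 of 20 cases (15 adjusted over the list alone; median log2 fold change 3.10; camera adjusted p = 1.3e-32, and adjusted p = 0.062 with an estimated correlation) and summed to 800 and 1154 CPM.

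Further lists at week 2 passed with few members. Small leucine-rich proteoglycan, protease and transcription factor genes were called up (2, 2 and 4 rose; camera adjusted p of 0.036, 0.038 and 0.03, and adjusted p = 0.63, 0.37 and 0.23 with an estimated correlation), as were endothelial and epicardial markers (1 rose and 1 fell, and 0; camera adjusted p of 0.0014 and 0.0017, and adjusted p = 0.44 for both with an estimated correlation). Basement membrane genes were called down (1 fell; camera adjusted p = 0.037, and adjusted p = 0.63 with an estimated correlation). The proteoglycan call was lost without any 1 of 9 libraries, and the protease and basement membrane calls without any 1 of 6. The epicardial and transcription factor calls were lost without week 2 replicate 1, in which epicardial markers summed to 223 CPM, against 71.3 CPM in the other week 2 library. At week 2, 283 genes passed in edgeR, 215 higher and 68 lower, and DESeq2 called 791. Of 64 named genes that passed, 34 kept their call with each library left out in turn. Both week 2 libraries had Y-linked reads and the uninjured libraries next to none, so these reads and the group cannot be told apart in this contrast. With the Y-linked term edgeR called 60, and in a fit of the 2 groups alone 171. Without uninjured replicate 2 it called 134, without week 2 replicate 2 164, and without week 2 replicate 1, the library with 4.21% mitochondrially encoded counts, 450.

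At week 4 cartilage and tendon genes stood at their highest summed levels, 17750 and 15920 CPM against 5310 and 5580 CPM in uninjured hearts. A sum is weighted to the most abundant members. The median log2 fold change of the list was 1.99, below the 2.71 of week 2 and the 2.34 of day 7. Above both uninjured libraries stood 17 of 27 members at week 4, 18 at week 2 and 16 at day 7. Comp (ENSMUSG00000031849, chromosome 8 at 70373558 to 70382066) reached 3440 ± 565 CPM, a log2 fold change of 5.54 ± 0.62, a call lost without either uninjured library. Cilp, a cartilage intermediate layer protein gene, stood at 1650 ± 199 against 148 ± 22.7 CPM, a call lost without either uninjured, day 3, day 7 or week 4 library, and the tenomodulin gene Tnmd was higher by 3.86 ± 0.66 on the log2 scale, a call lost without uninjured replicate 2. Chad and Cilp2, further cartilage genes, had 326 ± 141 and 69.8 ± 41.7 CPM against 62.1 ± 11.2 and 1.07 ± 1.51 CPM, and neither passed (edgeR adjusted p = 0.49 and 0.15). In all 7 of 27 genes of the list rose (12 adjusted over the list alone; median log2 fold change 1.99; camera adjusted p = 4e-13, and adjusted p = 0.14 with an estimated correlation). Fibromodulin (Fmod) rose to 1200 ± 148 from 115 ± 7.19 CPM and Meox1, a homeobox transcription factor gene, to 551 ± 14.2 from 265 ± 15.6 CPM, both lost without any 1 of the uninjured and week 4 libraries.

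Collagen and glycoprotein genes rose in 18 of 34 cases at week 4 (25 rose and 1 fell adjusted over the list alone; median log2 fold change 1.47; camera adjusted p = 2.6e-38, and adjusted p = 0.12 with an estimated correlation) and crosslinking genes in 8 of 26 (13 adjusted over the list alone; camera adjusted p = 7.1e-16, and adjusted p = 0.062 with an estimated correlation). Postn stood at 2950 ± 368 CPM and Lox at 627 ± 203 CPM. Wnt and TGF-beta genes rose in 6 of 23 and 6 of 30 cases (camera adjusted p of 2.4e-10 and 7.1e-07, and adjusted p = 0.062 and 0.15 with an estimated correlation). The Wnt antagonist gene Frzb stood at 715 ± 64.1 against 192 ± 2.87 CPM and Tgfb3 at 600 ± 30.7 against 95.3 ± 13.5 CPM. Contractile genes rose in 3 of 24 cases (12 rose and 2 fell adjusted over the list alone; camera adjusted p = 2.5e-11, and adjusted p = 0.21 with an estimated correlation). Resident fibroblast genes fell in 2 of 31 cases (14 fell and 1 rose adjusted over the list alone; median log2 fold change −0.66; camera adjusted p = 5.5e-09, and adjusted p = 0.37 with an estimated correlation). Ccl11, Adh1 and Lsamp had log2 fold changes of −7.13 ± 0.78, −5.09 ± 0.78 and −3.55 ± 0.52, the call of Adh1 being lost without either week 4 library. Macrophage markers rose in 5 of 20 cases (9 adjusted over the list alone; median log2 fold change 2.11; camera adjusted p = 3.8e-12, and adjusted p = 0.16 with an estimated correlation) and summed to 328 and 464 CPM.

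Fatty acid and heat shock genes were called down at week 4 (2 fell in each; camera adjusted p of 0.0026 and 0.018, and adjusted p = 0.31 and 0.53 with an estimated correlation), as were oxidative phosphorylation, cardiomyocyte and mitochondrially encoded genes, in which no member fell by the gene test (camera adjusted p of 0.0039, 0.043 and 1.8e-06, and adjusted p = 0.63, 0.59 and 0.43 with an estimated correlation). Small leucine-rich proteoglycan, transcription factor, glycolysis and endothelial genes were called up (3, 3, 1 and 1 rose; camera adjusted p of 0.02, 0.018, 0.0068 and 0.0097, and adjusted p = 0.59, 0.21, 0.39 and 0.56 with an estimated correlation), the proteoglycan call being lost without any 1 of 9 libraries. The heat shock and cardiomyocyte calls were lost without uninjured replicate 2 or week 4 replicate 1, and the endothelial call without uninjured replicate 2. In all 348 genes passed in edgeR at week 4, 277 higher and 71 lower, and DESeq2 called 867. Of 69 named genes that passed, 28 kept their call with each library left out in turn. With the Y-linked term edgeR called 175, and in a fit of the 2 groups alone 653. Without uninjured replicate 2, week 4 replicate 1 or week 4 replicate 2 it called 101, 143 and 154.

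**Figure D2:**
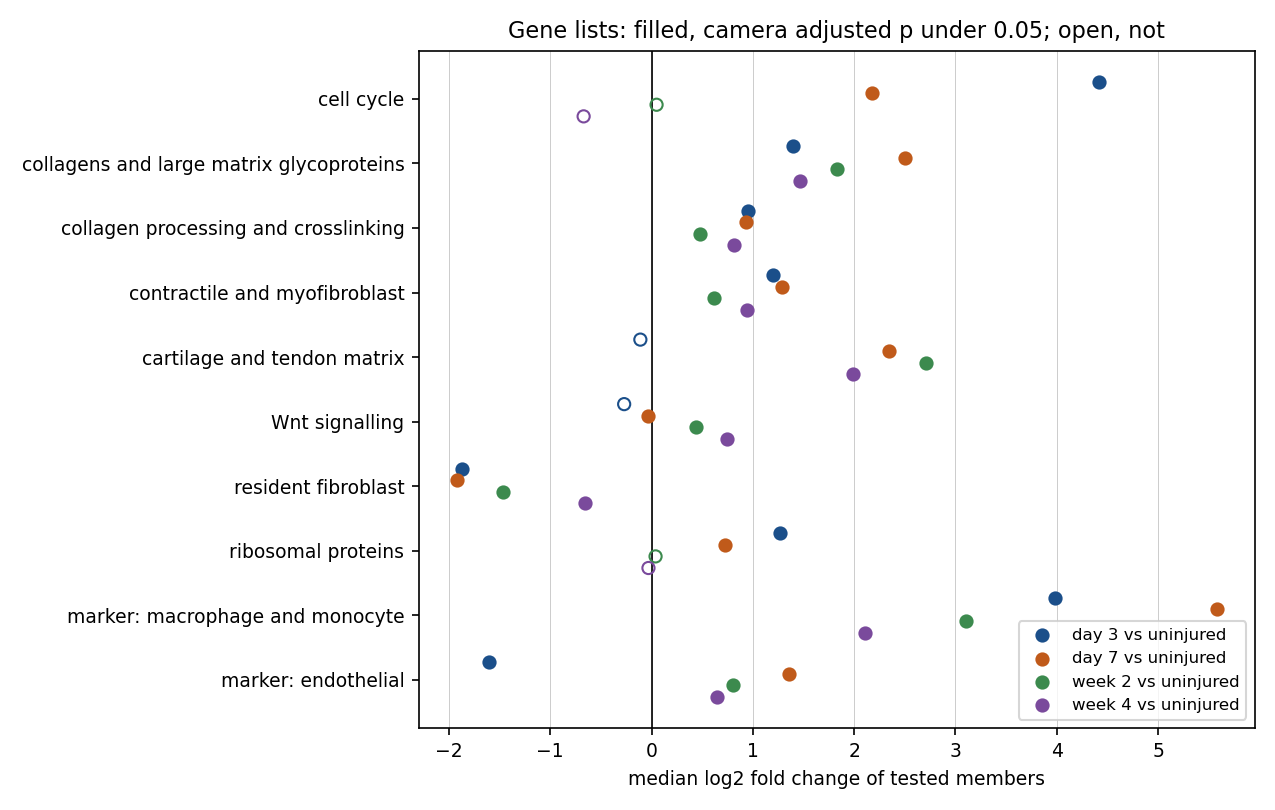
Median log2 fold change of the tested members of 10 gene lists (vertical axis) at each time against uninjured, with filled points where camera gave an adjusted p under 0.05 and open points elsewhere. The cell cycle list stood at 4.42 at day 3 and 2.18 at day 7 and was not called at week 2 or week 4, while the collagen and glycoprotein list was called at all 4 times; no call of any list held with an estimated correlation.

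From day 3 to day 7 cell cycle genes fell in 5 of 35 cases (19 adjusted over the list alone; median log2 fold change −1.99; camera adjusted p = 1.2e-21, and adjusted p = 0.12 with an estimated correlation). Top2a, the DNA topoisomerase gene of dividing cells, stood at 56.1 ± 3.17 against 256 ± 69.4 CPM, a call lost without any 1 of 4 libraries. Endothelial markers rose in 12 of 16 cases (13 adjusted over the list alone; median log2 fold change 2.94; camera adjusted p = 2.5e-32, and adjusted p = 0.062 with an estimated correlation). Erg stood at 35.6 ± 14.7 against 0.948 ± 0.0865 CPM. Macrophage markers (1 rose of 20; median log2 fold change 1.47) and pericyte and smooth muscle markers (1 of 14; median 1.74) were called up too, with camera adjusted p of 2.3e-08 and 4.5e-09, and adjusted p = 0.21 and 0.16 with an estimated correlation. So were Schwann (1 rose of 7) and erythroid markers (0 of 7), with camera adjusted p of 0.013 and 0.039, and adjusted p = 0.23 and 0.62 with an estimated correlation. The Schwann call was lost without day 3 replicate 2 or day 7 replicate 2 and the erythroid call without any 1 of 8 libraries. Collagen and glycoprotein genes rose in 7 of 34 cases (18 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.5e-15, and adjusted p = 0.28 with an estimated correlation). Col8a2 was higher by 3.41 ± 0.50 on the log2 scale, and the elastin gene Eln stood at 671 ± 105 against 37.5 ± 30.8 CPM. Aplnr, the apelin receptor gene, rose by 4.06 ± 0.54, and Tafa5 and Gask1a by 4.19 ± 0.73 and 4.08 ± 0.84. The retinoic acid synthesis gene Aldh1a2, the DNA polymerase gene Pola1, Tpx2 and Tlcd2 had log2 fold changes of −3.03, −3.29, −3.10 and −2.77. The step held 206 genes, 123 higher and 83 lower, in edgeR and 982 in DESeq2. A fit of the 2 groups alone gave 119 genes, and leaving out day 3 replicate 1, day 3 replicate 2 or day 7 replicate 2 gave 418, 33 and 31. Of 41 named genes that passed, 7 kept their call with each library left out in turn, and Eln, Tafa5, Gask1a, Col8a2 and Tpx2 were not among them.

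From day 7 to week 2 cell cycle genes fell in 4 of 35 cases (19 adjusted over the list alone; camera adjusted p = 3.6e-20, and adjusted p = 0.12 with an estimated correlation), Cenpe being at least 146-fold lower at week 2, where it had no counts. Macrophage markers fell in 1 of 20 cases, Cd68 at 18.8 ± 0.297 against 108 ± 4.83 CPM (13 adjusted over the list alone; median log2 fold change −2.26; camera adjusted p = 4.3e-16, and adjusted p = 0.13 with an estimated correlation). With no member passing, endothelial markers were called down and cardiomyocyte and epicardial markers up (camera adjusted p of 0.027, 0.043 and 0.017, and adjusted p = 0.59, 0.59 and 0.57 with an estimated correlation). All 3 were lost without week 2 replicate 1. The endothelial and epicardial calls were also lost without day 7 replicate 2, and the cardiomyocyte call without uninjured replicate 2 or day 7 replicate 1. Mitochondrially encoded genes were called up with no member passing (median log2 fold change 0.96; camera adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation). That call was lost without uninjured replicate 1, day 3 replicate 2, day 7 replicate 1 or week 2 replicate 1. Col1a1 had a log2 fold change of −2.15 ± 0.42 (edgeR adjusted p = 0.048, passed with 3 of the 10 libraries left out in turn), and the lysyl oxidase family gene Loxl2 of −2.10 ± 0.24. The innate immunity gene Ptx3 and the hyaluronan synthase gene Has1 rose by 2.34 ± 0.27 and 2.07 ± 0.36. The step held 97 genes in edgeR, 29 higher and 68 lower, and 1046 in DESeq2. The Y-linked term left 20 genes, a fit of the 2 groups alone 6 and a minimum of 10 counts in 4 libraries 52. Leaving out uninjured replicate 1 or 2 gave 224 and 233, day 3 replicate 1 157, day 7 replicate 1 or 2 424 and 4, and week 2 replicate 1 or 2 298 and 39. Of 27 named genes that passed, 3 kept their call with each library left out in turn, and Ptx3, Has1 and Cd68 were lost without day 7 replicate 2.

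From week 2 to week 4, 91 genes passed in edgeR, 68 higher and 23 lower. Cthrc1 had a log2 fold change of −2.60 ± 0.28 (290 ± 48.9 against 1760 ± 500 CPM), the fibrillin gene Fbn2 of −2.69 ± 0.43, and the macrophage marker gene Ms4a7 of −2.50 ± 0.47. The cardiac transcription factor gene Gata4 rose to 75.5 ± 26.9 from 12.7 ± 0.670 CPM. Macrophage markers fell in 1 of 20 cases (4 adjusted over the list alone; camera adjusted p = 2.2e-08, and adjusted p = 0.21 with an estimated correlation). Epicardial markers and mitochondrially encoded genes (median log2 fold change −1.19) were called down with no member passing, with camera adjusted p = 0.00027 for both, and adjusted p = 0.41 and 0.57 with an estimated correlation. Both calls were lost without week 2 replicate 1, the library with 4.21% mitochondrially encoded counts. The other week 2 library, replicate 2, was the one set apart on the third principal component. DESeq2 called 905 genes, the Y-linked term left 5 and a fit of the 2 groups alone 0, where 2214 genes had an unadjusted p under 0.05 in the fit of all groups. Leaving out uninjured replicate 1 or 2 gave 154 and 146, week 2 replicate 1 or 2 702 and 3, and week 4 replicate 1 or 2 7 and 55. Of 18 named genes that passed, 1 kept its call with each library left out in turn, and Fbn2, Ms4a7 and Gata4 were lost without week 2 replicate 2 or week 4 replicate 1.

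Between day 7 and week 4, 362 genes passed in edgeR, 134 higher and 228 lower at week 4. Macrophage markers fell in 13 of 20 cases (17 adjusted over the list alone; median log2 fold change −3.59; camera adjusted p = 8.6e-33, and adjusted p = 0.062 with an estimated correlation). The lysozyme gene Lyz2 stood at 81.1 ± 33.5 against 1240 ± 483 CPM. Cell cycle genes fell in 8 of 35 cases (23 adjusted over the list alone), collagen and glycoprotein genes in 10 of 34 (15), interferon genes in 8 of 32 (17) and ribosomal protein genes in 11 of 40 (36), with camera adjusted p of 1e-23, 1.5e-11, 4.5e-15 and 9.7e-22, and adjusted p = 0.12, 0.37, 0.21 and 0.32 with an estimated correlation. Endothelial (2 fell of 16) and neutrophil markers (0 of 8) were called down as well (camera adjusted p of 0.0095 and 0.043, and adjusted p = 0.56 and 0.37 with an estimated correlation). Both were lost without day 7 replicate 2, and the neutrophil call without either week 4 library. Postn and Cthrc1 had log2 fold changes of −2.07 ± 0.31 and −3.27 ± 0.29, while Gsn rose by 3.57 ± 0.56 to 29400 ± 2700 CPM and Comp by 2.67 ± 0.54, calls that were lost without either uninjured, day 7 or week 4 library and, for Comp, either week 2 library. Of 65 named genes that passed, 4 kept their call with each library left out in turn, and the call of Postn was lost without day 7 replicate 2. DESeq2 called 1308 genes and edgeR with the Y-linked term 221. Leaving out day 7 replicate 2 or week 4 replicate 1 or 2 gave 32, 39 and 126, and leaving out week 2 replicate 1 or 2 gave 567 and 578.

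In ATAC-seq the peak lists were longest at day 3. Uninjured libraries had 63901 and 71909 peaks, day 3 libraries 105695 and 107798, day 7 libraries 93724 and 88332, week 2 libraries 77947 and 79702, and week 4 libraries 69238 and 70195. Peaks of the 10 lists merged into 143334 regions, of which 38936 had a peak in all 10 libraries. A region counted as gained when both libraries of a time had a peak there and neither uninjured library did, and as lost in the reverse case. At day 3, 24687 regions were gained and 1556 lost, against 427 to 1160 regions in the splits that pair 1 library of each group. Day 7 had 13312 gained and 3393 lost (crossed splits 261 to 1929), week 2 7281 and 3811 (583 to 1510) and week 4 3958 and 5270 (523 to 1614). With the 63901 peaks of highest −log10 q from each library, the gained and lost regions became 8824 and 5777 at day 3, 6620 and 6334 at day 7, 4714 and 5224 at week 2 and 3710 and 5301 at week 4. After such a cut a region can count as gained or lost although a full list holds a weaker peak there. The peak lists carry no read depth, which sets how many peaks can be called, and with 2 libraries per group there are 3 splits, too few for a test. Leaving out 1 library loosens the criterion. Without replicate 1 of day 3 the gained regions came to 39592, and without replicate 1 or 2 of the later times to 23357 and 25691 at day 7, 13847 and 14442 at week 2 and 11465 and 9954 at week 4. Without uninjured replicate 2 they came to 11529 at week 2 and 7241 at week 4. The lost regions came to 4774, 8135, 9199 and 11310 at the 4 times without uninjured replicate 1 and to 3602, 6166, 6768 and 8639 without uninjured replicate 2. They came to 2694 without day 3 replicate 1, 7832 without day 7 replicate 1, 6420 without week 2 replicate 2 and 8601 without week 4 replicate 1. Between consecutive times 2611 regions were gained and 12385 lost from day 3 to day 7 (crossed splits 745 to 2229), 1306 and 5134 from day 7 to week 2 (935 to 2639) and 1078 and 4151 from week 2 to week 4 (1342 to 1754). With equal peak numbers these became 3561 and 5092, 1798 and 2079, and 1640 and 2285. Between day 7 and week 4, 1319 were gained and 9905 lost (crossed splits 706 to 2156), or 2910 and 4121 with equal peak numbers. Of the deposited peaks, the gained regions from day 7 to week 2 and to week 4 lay within the range of their crossed splits, and those from week 2 to week 4 below it. With equal peak numbers they lay above the highest crossed splits of 1533, 1386 and 1334.

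**Figure D3:**
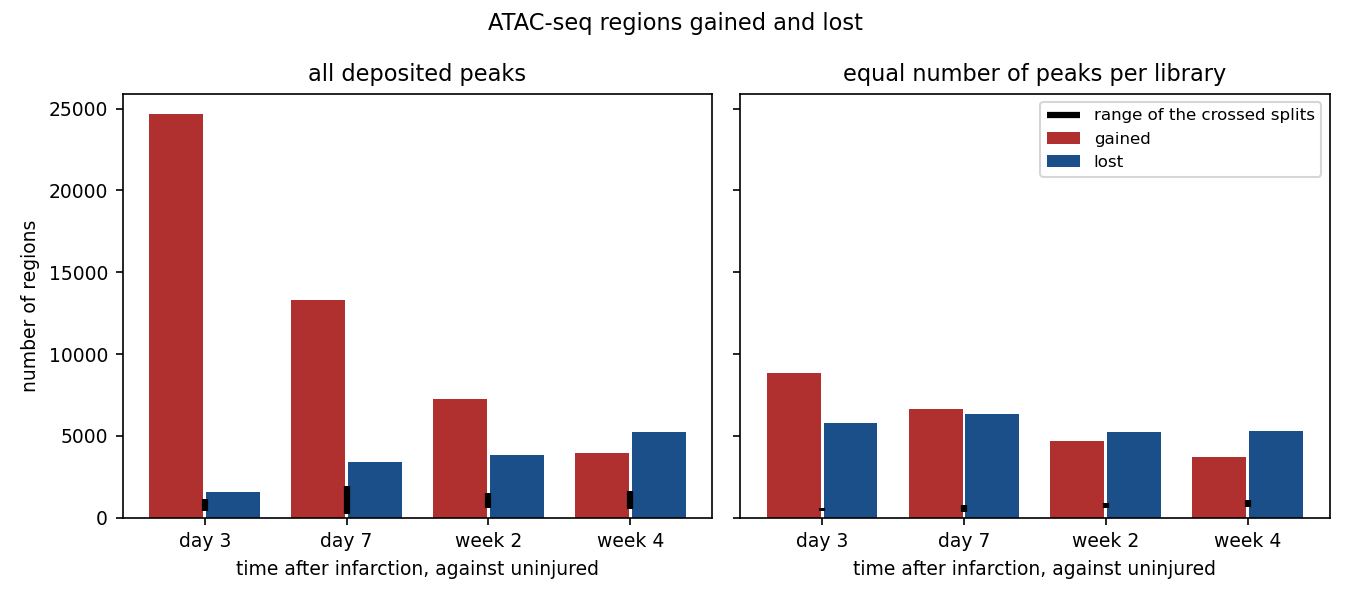
Number of ATAC-seq regions gained (red bars) and lost (blue bars) at each time against uninjured, from all deposited peaks (left) and from an equal number of peaks per library (right), with black lines for the range of the crossed splits. At day 3 the bars stood at 24687 and 1556 on the left and at 8824 and 5777 on the right, above the highest crossed split of 609 regions with equal numbers.

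The region with the strongest signal among those gained at day 3, day 7 and week 2 lay inside the span of Camk1d, a calcium/calmodulin-dependent kinase gene, on chromosome 2 at 5379034 to 5379384 (mm10), 351 bp wide, with the authors' fold enrichment between 52.1 and 67.5 in the 6 libraries of these times and no peak in the uninjured or week 4 libraries. Camk1d RNA had log2 fold changes of −2.10 at day 3 and −3.73 at day 7 (edgeR adjusted p = 0.0131 and 0.00104) and of −1.78 at week 2, which did not pass (edgeR adjusted p = 0.0887). A region on chromosome 9 at 35305223 to 35305589, 27492 bp from Rpusd4, had a peak in the 8 libraries after MI and in neither uninjured library. Rpusd4 RNA did not pass at day 7, week 2 or week 4 (edgeR adjusted p = 0.347, 0.959 and 0.416). Prrx2, which holds another gained region, did not pass at week 4 (edgeR adjusted p = 0.379). The regions at Camk1d and near Rpusd4 are narrow beside the median region width of 1170 bp, and no list of regions prone to spurious signal was used here. At day 3 a gained region on chromosome 12 at 55388796 to 55394315 covered part of the proteasome gene Psma6, whose RNA rose by 1.14 on the log2 scale, and at day 7 one on chromosome 8 at 61644933 to 61649476 lay in the actin-associated gene Palld, whose RNA rose by 2.77. Among lost regions, one on chromosome 3 at 60964907 to 60966227 lay 36568 bp from the purinergic receptor gene P2ry1, whose RNA had a log2 fold change of −2.34 at week 2 (edgeR adjusted p = 0.0414). The other lost regions of strongest signal lay at or near Il12b, Efcab6 and Usp29 at day 3, Olfr520 and Impg2 at day 7, Col23a1 at week 2 and week 4, and Pgbd5 and Aldh3a2 at week 4. None of those with tested RNA passed: edgeR gave adjusted p = 0.818 for Usp29, 1 for Impg2, 0.956 and 0.924 for Col23a1, 0.627 for Pgbd5 and 0.737 for Aldh3a2. Usp29 and, at week 2, Col23a1 had positive log2 fold changes beside a lost region.

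Runx1 (chromosome 16, 92601466 to 92826149) had 45 regions assigned to it within 100 kb, with a peak in 15 of them in each uninjured library, 38 and 36 at day 3 and 27 and 28 at week 4, with 16, 11, 10 and 8 regions gained at the 4 times and 0, 0, 0 and 1 lost. With equal peak numbers 6, 5, 6 and 8 were gained and 0, 0, 0 and 1 lost. Postn had 36, with peaks in 11 and 12 in uninjured libraries, 30 and 27 at day 3 and 14 and 13 at week 4, with 12, 6, 4 and 2 gained and none lost, or 3, 3, 2 and 2 gained and 1, 0, 0 and 0 lost with equal peak numbers. Col1a1 and Comp had 10 and 3 regions and none gained or lost (with equal peak numbers 1 at Col1a1 was lost at day 3), although the RNA of both changed. Tcf21 had 15, of which 1, 1, 0 and 0 were gained and 0, 2, 2 and 1 lost, or 0 gained and 2 lost at each time with equal peak numbers. Of all peaks 22.1% ± 1.06 (SD, n = 2) lay within 1 kb of an end of a gene span in uninjured libraries, 17.2% ± 0.0707 at day 3, 18.5% ± 0.424 at day 7, 20.1% ± 0.212 at week 2 and 21.9% ± 0.354 at week 4.

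Regions that changed were compared with genes that changed, over 14942 genes. Genes that fell had a lost region nearest to them more often than other genes at each time, with odds ratios of 3.73 at day 3, 4.90 at day 7, 6.14 at week 2 and 6.13 at week 4. The crossed splits gave 2.31 to 2.92, 1.80 to 2.36, 1.11 to 2.17 and 0.566 to 1.76. Genes that rose had a gained region nearest to them more often at day 7 (odds ratio 1.80; 46.0% against 32.1%), week 2 (4.04) and week 4 (5.19), where the crossed splits gave 0.988 to 1.48, 0.902 to 1.65 and 0.939 to 1.99. At day 3 the odds ratio was below 1, at 0.822 (43.0% against 47.9%, crossed splits 0.463 to 0.793), and with equal peak numbers it was 0.903 and did not pass. For regions within 1 kb of a gene end, gained regions and rising genes had odds ratios of 1.34, 2.14, 2.61 and 1.97 at the 4 times, the last with an adjusted p of 0.057, and lost regions and falling genes 2.74, 3.76, 6.88 and 5.56. All the other odds ratios named for the deposited peaks passed Fisher's exact test after adjustment over 16 tests, the largest adjusted p being 0.0097. At gene ends the ratios of 1.34 at day 3 and 6.88 at week 2 lay within the range of their crossed splits, which reached 1.63 and 7.15. Genes are not independent replicates, and a gene with more regions has more chances of a changed one. In 3 strata by region number, lost regions nearest to falling genes had odds ratios of 2.52, 3.38, 5.12 and 3.99 at the 4 times. Gained regions nearest to rising genes had 0.927, 1.88, 3.13 and 4.18, the first of which did not pass. The 2.52 at day 3 lay within the range of its crossed splits, which were not stratified.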

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

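The tests of macrophage markers, of scaling factors and of peak numbers, and the contrast of week 4 against day 3, were chosen after the results they measure had been seen; the test of matched short genes was written before.

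Genes and a gene list whose change from uninjured went in opposite directions at 2 times, with a test of the difference between those times, are given here. Endothelial markers were lower than in uninjured hearts at day 3 and higher at day 7, with a median log2 fold change between the times of 2.94 (12 of 16 genes passed; camera adjusted p = 2.5e-32, and adjusted p = 0.062 with an estimated correlation). Among them Pecam1, an endothelial adhesion gene, changed by −1.54 at day 3 and 1.19 at day 7, a difference of 2.73 ± 0.29 (SE; edgeR adjusted p = 0.0043). The matrix genes Prelp and Lamb2 and the secreted protein gene Dkk3 were lower than uninjured at day 3 and higher at week 4. The log2 differences from day 3 to week 4 were 3.22 ± 0.37 for Prelp, 3.03 ± 0.27 for Dkk3 and 3.01 ± 0.34 for Lamb2 (edgeR adjusted p = 5e-04, 0.00017 and 0.00038). The chemokine gene Ccl7 and the retinoic acid synthesis gene Aldh1a2 were higher at day 3 and lower at week 4, with log2 differences of −4.24 ± 0.47 and −3.48 ± 0.37 (edgeR adjusted p = 0.00065 and 0.00034). With single libraries left out, day 3 against uninjured no longer passed for Prelp (uninjured replicate 1, day 3 replicate 2) and Lamb2 (either uninjured library, day 3 replicate 2). Week 4 against uninjured no longer passed for Prelp and Lamb2 (uninjured replicate 2, week 4 replicate 1) and Ccl7 (these or week 4 replicate 2). The contrast of week 4 against day 3 was not run with libraries left out.

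The mitotic gene Kif2c was higher than uninjured at day 3 and day 7 and lower at week 2 and week 4, and Cenpe was higher at day 3 and day 7 and lower at week 2. Cenpe, with no counts at week 2, was at least 146-fold lower there than at day 7, and at week 4 it stood at 5.60 CPM against 5.39 CPM in uninjured hearts. Kif2c had 3 counts at week 4 against 2556 at day 3, a CPM ratio of 0.00112 (95% counting interval 0.00023 to 0.00327). Against 566 counts at day 7, Kif2c had 2 counts at week 2, a ratio of 0.00364 (0.00044 to 0.0132), and 3 at week 4, a ratio of 0.00533 (0.0011 to 0.0157). Against uninjured, Kif2c no longer passed at week 2 without week 2 replicate 2, or at week 4 without either week 4 library. What lies behind these reversals was not tested.

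Macrophage markers were higher after MI although the cells had been sorted on an eGFP gate, which would remove cells without the label; at day 7 all 20 markers stood above both uninjured libraries, with the abundant Lyz2 at a mean of 1240 CPM and Ctss at 466 CPM. At day 3 the median log2 fold change of the endothelial markers was −1.60. That argues against a general loss of sort purity only if cells reaching the gate kept their proportions after MI, which was not measured. At day 7, when macrophage markers had a median of 5.58, the endothelial median was 1.36 (0.80 at week 2 and 0.65 at week 4), so a loss of purity stays open at those times. Of the regions without an uninjured peak, with equal peak numbers, 8.64% at the marker genes and 8.16% at other genes were gained at day 7 (Fisher's exact p = 0.84), whereas gained against lost regions (7 and 0, Fisher's exact p = 0.016) decides little, since few regions there had an uninjured peak to lose. In the deposited peaks, 3 and 4 of the 20 marker genes had a peak within 1 kb of a gene end in the uninjured libraries. At day 3 it was 8 and 15, at day 7 14 and 16, and in each week 2 and week 4 library 5. With equal peak numbers 15 and 15 regions at these genes had a peak in the uninjured libraries. There were 26 and 28 at day 3, 25 and 38 at day 7, 23 and 19 at week 2 and 17 and 22 at week 4. Peaks there were thus more frequent at day 3 and day 7, but the share gained at day 7 was no higher than at other genes. They did not follow the RNA at each time. The markers summed to 986 and 1674 CPM at day 3 and to 800 and 1154 CPM at week 2, when few of the genes had an end peak. Macrophages that passed the sort, free RNA of other cells without their nuclei, and expression of these genes by lineage cells cannot be told apart. The last was not tested, and no value here excludes any of the 3.

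Ribosomal protein genes were higher at day 3, in 37 of 40 cases. The choice among the 3 scalings tried does not account for the rise, since the lowest median log2 fold change over them was 1.20. All 3 set the median of all genes near no change (−0.0206, −0.0359 and −0.0962). They could therefore differ little, and an assumption that they share was not tested. Of genes matched in span and expression 59 of 200 rose, with a median of 0.27 (bootstrap 95% interval 0.14 to 0.50). The interval stays below the 0.6 set for short genes as the whole cause, though its upper end passes the 0.3 set against them, and gene span is not transcript length. A change in the cells after MI and a difference in RNA handling between groups stay open and were not tested.

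More regions were gained than lost at day 3, 94.1% of those that changed. With equal peak numbers the share was 60.4%. That cut shortens the day 3 lists most, so a region with a weaker day 3 peak can count as lost. Lost regions went from 1556 to 5777, so the fall in the share is partly built into the cut. How much of the excess the larger number of peaks called in the day 3 libraries accounts for thus cannot be told. The larger number of peaks is argued against as the whole cause of the gained regions. With equal peak numbers 8824 were gained, against 609 in the highest crossed split. A wider opening of chromatin after MI and a difference in sequencing depth, which the peak lists do not give, both stay open for the excess.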

How the results depend on the processing

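Tests with a term for Y-linked reads, without genes of the Y chromosome, in strata by region number and without marker genes of other cells were chosen after the data were seen, and the other alternatives here were planned. The cause of each change below was not tested, except where stated.

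RNA counts of genes past the threshold kept within 1.5 times of their value with size factors, with the upper quartile, without genes of the Y chromosome, and with a minimum of 2-fold. With no filter on low counts they were 1846 (day 7 against uninjured), 796 (week 2), 971 (week 4), 814 (day 7 against day 3), 1029 (week 2 against day 7), 952 (week 4 against week 2), 1306 (week 4 against day 7) and 4148 (any difference). With at least 10 counts in 4 libraries, 52 genes passed from day 7 to week 2. In fits of the 2 groups alone, with fewer residual degrees of freedom by construction, 635 genes passed at day 7, 171 at week 2 and 653 at week 4 against uninjured. The same fits gave 119 from day 3 to day 7, 6 from day 7 to week 2 and 0 from week 2 to week 4 (edgeR). For that last step 2214 genes had an unadjusted p under 0.05 in the fit of all groups and DESeq2 called 905.

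DESeq2 called 2830, 2000, 791 and 867 genes at day 3, day 7, week 2 and week 4 against uninjured. It called 982 from day 3 to day 7, 1046 from day 7 to week 2, 905 from week 2 to week 4, 1308 from day 7 to week 4 and 4334 for any difference. With Y-linked reads as a term edgeR called 587 at day 7, 60 at week 2 and 175 at week 4 against uninjured, 20 from day 7 to week 2, 5 from week 2 to week 4 and 221 from day 7 to week 4. Both uninjured libraries lack such reads, so the term is partly confounded with the groups. Both week 2 libraries hold them, so for week 2 against uninjured Y-linked reads and group cannot be told apart within the 2 groups. The term is estimated there from the libraries of day 3, day 7 and week 4. With replicate block as a term the counts were 1784, 1109, 304 and 362 against uninjured, with no evidence of pairing between numbers. Of the list calls 0 held with an estimated correlation and fry called 59.

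Leaving out each library in turn, with the lone library of a group assumed to vary like the others, gave 677 to 2078 genes at day 3, 312 to 1315 at day 7, 134 to 450 at week 2 and 101 to 491 at week 4 against uninjured. Between times it gave 31 to 418 (day 3 to day 7), 4 to 424 (day 7 to week 2), 3 to 702 (week 2 to week 4) and 32 to 578 (day 7 to week 4), with 1458 to 2945 for any difference and 113 to 136 list calls. Over 559 results of named genes and 20 settings, 1412 values lost and 90 gained a call in the same direction, and 9675 stayed on their side of the threshold, 18 of the values that did not pass turning their sign. The 1 that reversed was Mki67 at week 2, with a log2 fold change of 4.80 without uninjured replicate 1, against −0.77 with all libraries and −1.75 without uninjured replicate 2 (neither passed). The 2 uninjured libraries thus differ in Mki67 by more than the change tested.

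With equal peak numbers, gained and lost regions were 8824 and 5777 at day 3, 6620 and 6334 at day 7, and 4714 gained at week 2. Lost regions were then 5092 from day 3 to day 7 and 2079 from day 7 to week 2. From week 2 to week 4 the same setting gave 1640 and 2285, and from day 7 to week 4 2910 and 4121. With a −log10 q of 5 or more, 8622 regions were gained at day 7 and 2163 at week 4. That threshold gave 1645 gained from day 3 to day 7, 2795 lost from day 7 to week 2, 343 gained from week 2 to week 4 and 669 gained from day 7 to week 4. With windows of equal width centred on summits 3019 regions were lost at day 3, and 4400, 2263, 1640 and 2115 were gained from day 3 to day 7, day 7 to week 2, week 2 to week 4 and day 7 to week 4. Requiring a larger share of a region to overlap kept all counts within 1.5 times.

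Leaving out a library asks for a peak in fewer libraries by construction. Gained regions were then 27515 to 39592 at day 3, 15083 to 25691 at day 7, 8951 to 14442 at week 2 and 5126 to 11465 at week 4, and lost regions 2308 to 4774, 4035 to 8135, 5588 to 9199 and 7306 to 11310. Between times 4180 to 9251 were gained and 15715 to 24441 lost (day 3 to day 7), 2144 to 5545 and 8612 to 16498 (day 7 to week 2), 2173 to 6499 and 7221 to 11071 (week 2 to week 4), and 1925 to 5975 and 14084 to 23147 (day 7 to week 4). The odds ratio of gained regions and rising genes at day 3 no longer passed with equal peak numbers (0.903) or in 3 strata by region number (0.927). At gene ends that ratio was 1.38 with equal peak numbers and no longer passed at day 3, and 2.49 in 3 strata by mean expression at week 4, where it passed. Within 2 kb of a gene end lay 25.2%, 20.8%, 22.2%, 23.8% and 25.5% of peaks from uninjured to week 4, more by construction. Similarity of libraries of a group kept p = 0.00106 in each alternative with all libraries (exact permutation). Leaving out marker genes of other cells, and regions within 50 kb instead of 100 kb, changed no planned association of genes with regions.

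The planned analysis of motifs and its 3 alternatives were not run, since no genome sequence was held. At 2 libraries per group the simulated recovery of 2-fold changes was 5% (day 3 against uninjured, edgeR), so a gene that did not pass is not shown to be unchanged.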

Other observations

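Associations of genes with regions that were not planned, read after the data were seen, are given here. At day 7, 6.39% of the genes that rose and 11.5% of other genes had a lost region nearest to them (odds ratio 0.527, crossed splits 0.988 to 1.48; Fisher's exact adjusted p = 0.00011). At week 2 the shares were 6.51% and 12.2% (odds ratio 0.499, crossed splits 0.902 to 1.65; adjusted p = 0.023, and 0.059 without marker genes of other cells). At day 3, 60.8% of the genes that fell and 46.9% of other genes had a gained region nearest to them (odds ratio 1.75; Fisher's exact adjusted p = 6.1e-11). That ratio lies below the 2.31 to 2.92 of the crossed splits and was 0.92 in 3 strata by region number (adjusted p = 0.5), so it is no evidence of a link between the 2 changes.

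Among the 6 ATAC-seq libraries whose codes begin with A, the mean Jaccard index was 0.692 within groups and 0.573 between groups (exact p = 0.022), a test added after the data were seen. That test holds 2 pairs of the same group, uninjured and day 3. Over all libraries the index between groups was 0.585 for libraries with the same code letter and 0.576 for those with different letters. Both uninjured and both day 3 libraries have codes with A, and both week 4 libraries codes with B. Code letter and group thus cannot be told apart for week 4 against uninjured, and these indices do not exclude an effect of the code. Genes of the Y chromosome held 0.0124% of counts in day 3 replicate 1, 0.0252% in day 7 replicate 2, 0.0429% and 0.0426% in the week 2 libraries, 0.0314% in week 4 replicate 2, and under 0.001% in the other 5 RNA libraries, both uninjured ones among them.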
